A study of Mus musculus with 6 samples.

How the data were processed

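Total RNA of double-negative mouse thymocytes was labelled with biotin and hybridised to 6 arrays with 1 colour, per the labels. Groups and replicate numbers were taken from the sample labels: 3 arrays of cells from Rag2-/- mice and 3 of wild-type cells transduced with TLX3. Per the labels' protocols, double-negative cells were obtained by depleting cells carrying CD4 or CD8 on magnetic beads, followed by flow sorting. The gate that the labels name removes CD4- and CD8-bearing cells, and they name no antibody against myeloid, NK or epithelial cells. Whether the Rag2-/- cells were cultured is not clear from the labels.

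The deposited values are log2 expression values per probe set, made with RMA, a method of background correction, quantile normalization and probe summary, in the affy package under R 2.9.0, per the submitters' processing notes. RMA brings arrays to 1 distribution of probe signals when they are run together. The deposited probe-set values still differed in spread between the groups, which can pull bright transcripts down and dim ones up in the arrays with the narrower range. The genome build used by the authors is not given in the sources used here.

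The table holds 34760 probe sets. The 6568 numbered before the genome-ordered ones have no gene listed, were taken to be controls without an annotation that shows it, and were left out. The remaining 28192 were tested. Of these, 22961 have a gene in the platform annotation, 21640 with a single symbol and 1321 with several, and 5231 have none listed. No gene was named from a probe set with several symbols. Each gene was represented by its single-symbol probe set with the highest mean over all arrays, which gave 19937 genes, 954 of them with more than 1 probe set. Of the symbols, 19918 were found in a gene table of assembly GRCm38.p6, which was used for names, chromosomes and gene lengths. Tcf7, Lck and Cdkn1a had no single-symbol probe set and were not analysed here.

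Differences were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with no covariate and no further normalization, and p-values were adjusted by Benjamini-Hochberg over the 28192 probe sets. A gene was called at an adjusted p under 0.05 with an absolute log2 difference of at least 1. Folds are 2 to the power of the absolute log2 difference and are given where both group means lay above the array medians. The groups, tests, thresholds, gene lists, rule for named genes and all alternatives but cyclic loess were chosen before the data were examined. The named genes are a fixed set of T-lineage and leukaemia genes, the 12 largest rises and 12 largest falls among called, non-overlapping genes whose higher group mean lay above the median of probe sets, up to 3 called members per list and direction, and the sex-linked list. Members that were not called are named with their values, and so are further called members where a list had few calls, which were chosen after their values were seen.

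The 30 gene lists with at least 5 measured members were tested with limma camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Lists were also compared with 10000 random lists matched on mean level in 50 bins and, as chosen after the data were seen, with 10000 matched on mean level and gene length in 10 bins each. Chromosomes were tested in the same way over genes above the median level. The pipeline was tested on simulated values with the means and spread of these arrays. Over 28192 probe sets it recovered 89.6% of 67 differences of 1.5 log2 units, 98.5% of 67 differences of 2 and 100% of 66 differences of 3. It made 0 false calls, and called the 1 shifted list and 0 of 30 unchanged ones. The simulated values had no correlation between genes and no difference in signal range between the groups. These counts therefore do not measure false calls in the real data, for genes or for lists. Plots were drawn with matplotlib 3.10.9.

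The alternatives were quantile normalization of the values again, equal array medians, cyclic loess (added after the signal range was seen to differ), filters on dim probe sets, an intensity trend with robust estimation, array weights, the replicate number as a block, the mean of a gene's probe sets, no minimum difference, limma treat, and leaving out each array. A planned filter on probe set names could not be run, since the probe sets of this platform carry plain numbers.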

Results

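Transcript levels were measured on 6 Affymetrix arrays of mouse double-negative (DN) thymocytes, the immature T-cell precursors of the thymus that carry neither CD4 nor CD8 on their surface. The arrays form 2 groups of 3. The first group holds DN thymocytes of mice lacking Rag2, a recombinase needed to assemble antigen receptor genes, whose thymocytes stop at the DN stage. The second holds DN thymocytes of wild-type mice that were given a retrovirus carrying TLX3, a homeobox gene switched on in a subset of T-cell acute lymphoblastic leukaemia (T-ALL), and then grown on OP9-DL1, a stromal cell line that presents a Notch ligand. The labels call the first group control and the second tumoral. No array of wild-type cells given an empty virus was analysed here, so genotype and virus differ together between the groups. Culture may differ with them, since the labels leave unclear whether the Rag2-/- cells were cultured. The labels do not say whether replicates came from separate mice or cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision: the median SD of a probe set was 0.11 log2 units in the Rag2-/- group and 0.21 in the TLX3 group.

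Arrays of a group resembled each other more than those of the other group. The mean correlation across probe sets with the other arrays of its group was 0.993 to 0.994 for the Rag2-/- arrays. It was 0.976 for TLX3 replicate 1 and 0.981 for TLX3 replicates 2 and 3. The first principal component held 74.3% of the variance and parted the groups. The signal range differed: the interquartile range was 3.09 to 3.18 log2 units on the Rag2-/- arrays and 2.47, 2.85 and 2.75 on TLX3 replicates 1, 2 and 3. With that, 1194 olfactory and vomeronasal receptor genes, which thymocytes are not known to use, had a median log2 difference of 0.32 (TLX3 minus Rag2-/-, as everywhere in the text), against 0.03 after quantile normalization of the values again and -0.00 after cyclic loess. The median over all tested probe sets was 0.13, against 0.04 and 0.00 after the same rescalings. Gene length moved with the groups too: among 9964 genes above the median level, the 1993 with the longest gene length had a median log2 difference of -0.40 and the 1993 with the shortest 0.10. Detection calls were not used here. A group mean under the array medians (6.22 to 6.35) may be background, so a difference from such a level is one of deposited values, whose true size and rank are not known.

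The comparison asks how DN thymocytes carrying TLX3 differ in transcript level from DN thymocytes of Rag2-/- mice. Genes known as markers of thymic epithelium and of antigen-presenting cells were among those that fell. Prss16, a thymic epithelial serine protease, fell from 11.49 ± 0.59 to 5.89 ± 0.52 (SD, n = 3 in each group), the latter under the array medians. H2-Aa and Cd74, of MHC class II presentation, fell from 10.52 and 10.26 to 5.02 and 5.17, likewise under the medians. Among T-lineage genes, Ptcra, the partner of the T-cell receptor beta chain before the alpha chain is made, was 2.16-fold lower, while Id3, Nr4a1 and Egr1, which are induced by receptor signals in thymocytes, rose by 1.45, 1.80 and 1.44 from means under the array medians.

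Of 19937 genes, 1298 changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg) and an absolute log2 difference of at least 1, of which 288 were higher and 1010 lower in the TLX3 arrays. The falls were also the larger changes: 110 genes fell by at least 2 log2 units and 3 rose by that much. At the adjusted p alone, 8453 genes differed, 4595 of them higher and 3858 lower. The groups did not overlap for 58.3% of genes, where chance gives 10%. Against a minimum difference of 1 within the test itself (limma treat), 7 genes were higher and 122 lower.

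The gene named in the design was higher in the TLX3 arrays. Tlx3 was at 5.45 ± 0.07 in the Rag2-/- arrays and 6.69 ± 0.35 in the TLX3 arrays (SD, n = 3), with a log2 difference of 1.24 ± 0.18 (SE) and a limma adjusted p of 0.00103. It was higher in 3 of 3 TLX3 arrays, at 7.09, 6.52 and 6.45. Its paralog Tlx2 also rose, by 1.04, though it lost the call without TLX3 replicate 1 (0.99) or Rag2-/- replicate 2 (0.97), and Tlx1 stood at 0.74, below the minimum difference. The species of the TLX3 insert is not given in the sources used here, so the array value need not measure the insert. Rag2 did not differ past the threshold (log2 difference -0.30 ± 0.15 SE, limma adjusted p = 0.124) and was not lower in the arrays labelled Rag2-/-. Where its probes lie relative to the deleted part of the gene is not given in the sources used here, so this value does not check the labels. Rag1 was at 11.79 in the Rag2-/- arrays and 11.96 in the TLX3 arrays.

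**Figure D1:**
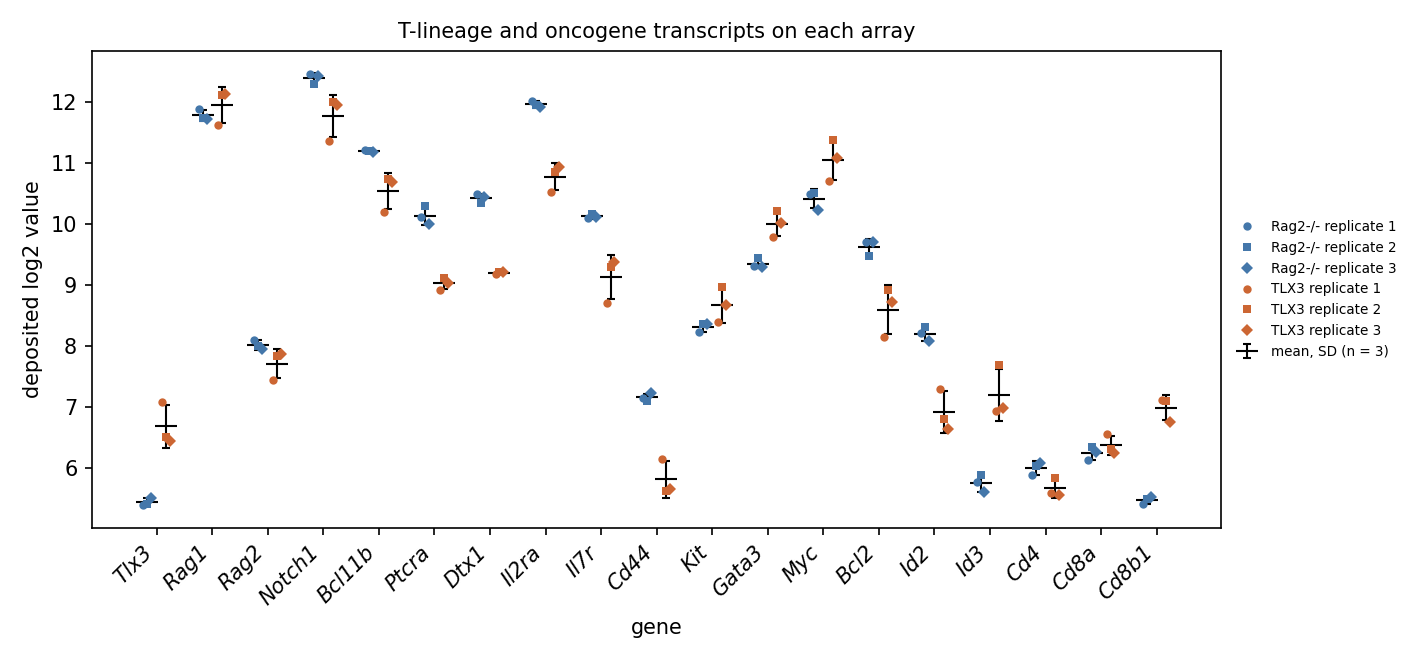
Deposited log2 values (vertical axis) of 19 T-lineage, oncogene and survival genes (horizontal axis) on each of the 6 arrays, blue for Rag2-/- and orange for TLX3, with a marker shape per replicate and black bars for the mean and SD of 3 arrays. Tlx3 lies at 6.45 to 7.09 in the TLX3 arrays against 5.40 to 5.52 in the Rag2-/- arrays, and Ptcra, Dtx1, Il2ra and Cd44 lie lower in all 3 TLX3 arrays.

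Genes that mark commitment to the T lineage and the DN3 stage were lower on balance (camera adjusted p = 0.00212, adjusted p = 0.674 with an estimated correlation). Of 25 measured, 3 fell, none rose and 22 were not called. Adjusted over the list alone, the counts were again 3 and 0. The 3 were Dtx1, a Notch-induced ubiquitin ligase (log2 difference -1.23), Il2ra, the CD25 surface marker of DN2 and DN3 cells (-1.19), and Ptcra (-1.11, or -0.97 after cyclic loess, where it was no longer called). Notch3 (-0.77), Bcl11b (-0.65), Notch1 (-0.62), Hes1 (-0.54), Runx1 (-0.50) and Cd3e (-0.50) passed the limma adjusted p but not the minimum difference, as did Gata3 in the other direction (0.66). Lef1 differed by 0.04. The median of the list was -0.38, against -0.18 for random lists matched on level and gene length, of which 5.01% were as low.

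Of 29 genes of T-cell receptor signalling, 4 fell, 25 were not called, and the counts adjusted over the list alone were the same. The 4 were Trat1 (-1.11), Cblb (-1.09), the kinase Fyn (-1.08) and the kinase Txk (-1.08). Trat1 and Fyn lost the call after quantile normalization again (-0.93 and -0.90), and Trat1 and Cblb without TLX3 replicate 1 (-0.97 and -0.96), and Trat1, Cblb and Fyn after cyclic loess (-0.94, -0.99 and -0.91). The camera adjusted p was 0.000158, and the adjusted p was 0.674 with an estimated correlation. The median was -0.60, against -0.28 for random lists matched on level and gene length, of which 0.15% were as low. The list of Notch targets had 3 of 20 lower, the same Dtx1, Il2ra and Ptcra, and was not called (camera adjusted p = 0.303), with a median of -0.15 that turned to 0.04 after quantile normalization again.

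Cytokine receptor and JAK-STAT genes had 4 of 29 lower, none higher and 25 not called, also adjusted over the list alone. Il2rb, a receptor chain for interleukins 2 and 15 carried by NK and memory T cells, fell by 2.54, as 13 of 20 NK markers fell, Cish was 2.78-fold lower, and Il2ra and Jak2 (-1.07) fell as well. Il7r, the interleukin 7 receptor, was 1.99-fold lower, just short of the minimum difference, and was called when the array medians were made equal (-1.06). The list was lower (camera adjusted p = 0.00113, adjusted p = 0.508 with an estimated correlation), with a median of -0.27 against -0.17 for such matched lists, of which 17.4% were as low. Genes of trafficking and adhesion split: Cd44 (-1.35), the integrins Itga6 (-1.20) and Itga4 (-1.13), Itgb2 (-1.09) and Itgb7 (-1.05) fell, and Ccr9, the receptor for the thymic chemokine Ccl25, rose by 1.59. Without TLX3 replicate 1, 2 members of the list were called lower instead of 5, with Itga6 (-0.97) and Itga4 (-0.89) among those that lost the call. The other 14 of 20 were not called, again with the same counts adjusted over the list alone, and the camera adjusted p was 0.0032, with an adjusted p = 0.417 with an estimated correlation (median -0.41, against -0.02 for lists matched on level and gene length, of which 0.42% were as low).

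Of 22 genes of the early progenitor and DN2 stages, 3 fell, namely Cd44, Cpa3 (-1.41) and Meis1 (-1.32), and none rose (camera adjusted p = 0.0888). Kit differed by 0.36 without passing the threshold. Of 22 genes of the DN4 to double-positive stages, Ccr9 and Cd8b1, the CD8 beta chain (1.52), rose, and Arpp21 (-1.35) and Themis (-1.02) fell. The camera adjusted p was 0.666 and the median was -0.03. Themis lost its call without TLX3 replicate 1 (-0.92) or Rag2-/- replicate 1 (-0.999). It was also not called after quantile normalization again (-0.93), after cyclic loess (-0.90) or with array weights (-0.93). Cd4 (-0.34) and Cd8a (0.12) were not called. Of 16 mature T-cell markers, Cd8b1 rose and Il2rb, Ms4a4b (-1.43), Gimap4 (-1.37) and Ctla4 (-1.28) fell (camera adjusted p = 0.0215, adjusted p = 0.417 with an estimated correlation). Il2rb is also on the NK marker list, of which 13 of 20 members fell, and Ms4a4b is known from NK cells too. The median of the mature list was -0.26, against 0.13 for lists matched on level and gene length, of which 0.85% were as low. Counts adjusted over the list alone equalled these in all 3 lists.

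Among 18 genes of the gamma-delta lineage and the early response to receptor signals, 5 rose and 1 fell. The rises were Nr4a1 (1.80 ± 0.14 SE), Id3 (1.45 ± 0.20), Egr1 (1.44 ± 0.16), Etv5 (1.14) and Il17a (1.00). Il17rb fell by 1.62. The list missed the threshold (camera adjusted p = 0.0888) and passed it as higher after quantile normalization again (0.0493), after cyclic loess (0.0407) and when probe sets under the median level (0.0101) or the 25th percentile (0.0427) were left out. Its adjusted p was 0.417 with an estimated correlation. Of 22 immediate early and stress genes, Nr4a1 and Egr1 rose and the antiproliferative Btg2 fell by 1.10 (camera adjusted p = 0.22). Btg2 lost its call after quantile normalization again (-0.97) and after cyclic loess (-0.96). Fos was at 0.49 and Jun at -0.49, both short of the minimum difference. Of 10 E proteins and Id factors, which oppose each other in thymocyte development, Id3 rose and Id2 (-1.29) and Tcf4 (-1.01) fell (camera adjusted p = 0.96). Id2 is also on the NK marker list, of which 13 of 20 members fell. Tcf4 was not called without TLX3 replicate 1 (-0.96), after quantile normalization again (-0.81), after cyclic loess (-0.83) or with array weights (-0.99). For these 3 lists too, the counts adjusted over the list alone were equal.

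Of 27 genes of G2 and mitosis, 4 rose, none fell and 23 were not called, also adjusted over the list alone. Cyclin A2 (Ccna2, 1.30 ± 0.12 SE), Cdk1 (1.19 ± 0.15), Ube2c (1.09) and Ccnb2 (1.02) were the 4, while Mki67 differed by -0.00. The camera adjusted p was 0.00206, with an adjusted p = 0.674 with an estimated correlation. Of 29 genes of DNA replication and the G1/S transition, Ccne1 rose by 1.07 and 28 were not called, in either adjustment (camera adjusted p = 0.00411, adjusted p = 0.724 with an estimated correlation). After quantile normalization again and after cyclic loess, 4 of them were called higher. Of 27 genes of ribosome biogenesis and MYC targets, 3 rose, also adjusted over the list alone: Fbl (1.36), Nolc1 (1.13) and the spermidine synthase Srm (1.10). A second probe set of Fbl gave 0.54, and Srm lost the call without Rag2-/- replicate 3 (0.98). The number called higher was 6 without TLX3 replicate 1, 8 after quantile normalization again, 6 after cyclic loess and 5 with array weights. The list was higher (camera adjusted p = 0.00101, adjusted p = 0.674 with an estimated correlation). Myc itself was at 0.64, past the limma adjusted p (0.0197) and short of the minimum difference.

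Few survival and leukaemia genes were called. Bcl2 fell by 1.03, a call lost without TLX3 replicate 1 (-0.81) and after quantile normalization again (-0.87), and Bbc3, a BH3-only killer, rose by 1.12, or 0.99 without Rag2-/- replicate 2 (BCL2 family, 14 measured, camera adjusted p = 0.855). After quantile normalization again and after cyclic loess, 3 of the family were called higher. Bcl2l11 (-0.84), Cdkn1b (-0.93, with a second probe set at -0.27) and Cdkn2a (0.84) passed the adjusted p only. Of 26 T-ALL oncogenes, Tlx3 and Tlx2 rose and none fell (camera adjusted p = 0.22). Their median was 0.37, against 0.12 for lists matched on level and gene length, of which 99.2% were as low. Fry called the oncogene list higher (adjusted p = 0.00437), and camera with an estimated correlation did not call it (adjusted p = 0.508). Of 26 T-ALL tumour suppressors, Fbxw7 fell by 1.25 on its brighter probe set, while a dimmer one gave 0.32 (camera adjusted p = 0.0575). That list passed as lower without Rag2-/- replicate 3, TLX3 replicate 2 or TLX3 replicate 3 (camera adjusted p of 0.0452, 0.0381 and 0.0339), and 3 members were called lower in the last case. Its adjusted p was 0.741 with an estimated correlation. Of 28 Polycomb and H3K27 genes, Phc3 fell by 1.15 and Rybp rose by 1.14 (camera adjusted p = 0.244). Phc3 was not called without TLX3 replicate 1 (-0.96), after quantile normalization again (-0.98), after cyclic loess (-0.98) or with array weights (-0.997). The rise of Rybp was on the brighter of 2 probe sets that gave 1.14 and 0.12. Ezh2 differed by -0.01. Of 22 CDK inhibitors and p53 targets, Bbc3 rose and Btg2 fell (camera adjusted p = 0.588). Counts adjusted over the list alone equalled these in the 5 lists. Btg2 was not called after quantile normalization again (-0.97) or after cyclic loess (-0.96).

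None of 16 genes of V(D)J recombination, 16 of glycolysis, 23 of oxidative phosphorylation or 17 of cholesterol synthesis was called, over all genes or adjusted over the list alone. By limma camera these lists had adjusted p of 0.139, 0.419, 0.999 and 0.666. At the limma adjusted p without a minimum difference, 8, 3, 7 and 2 of their members passed. After quantile normalization again, the glycolysis and cholesterol lists passed as higher (camera adjusted p = 0.0345 and 0.0443), as they did after cyclic loess (0.0226 and 0.0315). In that order the 2 lists had adjusted p of 0.888 and 0.932 with an estimated correlation. In the first setting 2 genes of glycolysis and 2 of oxidative phosphorylation were called higher, and 1 and 2 in the second.

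Of 25 myeloid and dendritic markers, 19 fell, none rose and 6 were not called. H2-Aa (-5.50), Cd74 (-5.09), H2-Ab1 (-4.19) and the lysosomal protease Ctss (-3.65) were among the 19. Of 15 thymic epithelial markers, 8 fell and 7 were not called. Prss16 (-5.60), the chemokine Ccl25 (-5.01, with a second probe set at -0.93) and keratin 18 (Krt18, -3.39) were among the 8, while Epcam (-0.03) and Aire (0.22) were not called. Of 20 natural killer (NK) and cytotoxic markers, 13 fell and 7 were not called, with Ccl5 at -3.68, Fcer1g at -3.10 and the NK receptor Ncr1 at -2.98, whereas Gzma stood at 0.76. Adjusted over the list alone, the counts were again 19, 8 and 13. The camera adjusted p was 1.35e-12 for the myeloid, 4.81e-07 for the epithelial and 5.13e-09 for the NK list. In the same order the adjusted p was 0.123, 0.417 and 0.123 with an estimated correlation. The 3 Rag2-/- arrays differed among themselves here: Prss16 was at 12.17 in replicate 3 and at 11.18 and 11.12 in replicates 1 and 2. Of the genes counted as myeloid, H2-Aa, Cd74 and H2-Ab1 were also highest in replicate 3 (10.83, 10.52 and 11.17), whereas Ctss was lowest there (9.52). Thymic epithelium is known to carry MHC class II as well.

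**Figure D2:**
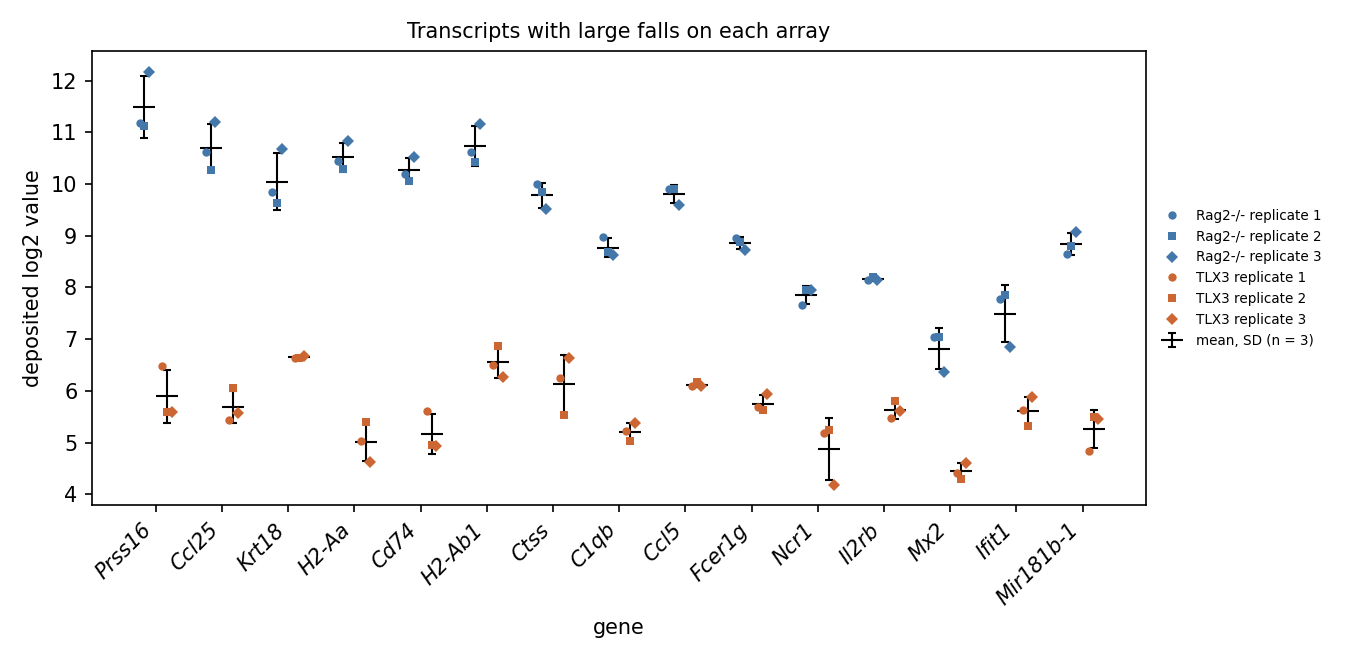
Deposited log2 values (vertical axis) of 15 genes with large falls (horizontal axis) on each of the 6 arrays, blue for Rag2-/- and orange for TLX3, with a marker shape per replicate and black bars for the mean and SD of 3 arrays. The epithelial genes Prss16, Ccl25 and Krt18 are highest in Rag2-/- replicate 3, and every gene shown is lower in all 3 TLX3 arrays.

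Of 23 interferon-induced genes, 16 fell, none rose and 7 were not called, also adjusted over the list alone. Mx2 fell by 2.37, Ifit3 by 2.03 and Ifit1 by 1.88, all to means under the array medians, whereas Bst2 differed by 0.06. The camera adjusted p was 4.23e-10, with an adjusted p = 0.484 with an estimated correlation. On Rag2-/- replicate 3, the array with the highest epithelial values, Mx2 was lowest of its group (6.36 against 7.05 on each of the others). Of 29 stromal markers, 5 fell and 24 were not called, also adjusted over the list alone: Vcam1 (-3.39), Cxcl12 (-1.61), Dcn (-1.41), Fn1 (-1.16) and Vim (-1.16). The fibrillar collagens were not called, with Col1a1 at 0.01 and Col1a2 at -0.11. The stromal list was lower (camera adjusted p = 0.0227, adjusted p = 0.626 with an estimated correlation), and lost the call without Rag2-/- replicate 3 or without TLX3 replicate 2 (camera adjusted p of 0.0781 and 0.07). Of 8 erythroid markers, Alas2 (-1.69) and Car2 (-1.58) fell (camera adjusted p = 0.12, or 0.0373 without Rag2-/- replicate 3; adjusted p = 0.674 with an estimated correlation). Of 14 B-cell markers, Pou2af1 rose by 1.18 (camera adjusted p = 0.666). Counts adjusted over the list alone were equal for both.

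**Figure D3:**
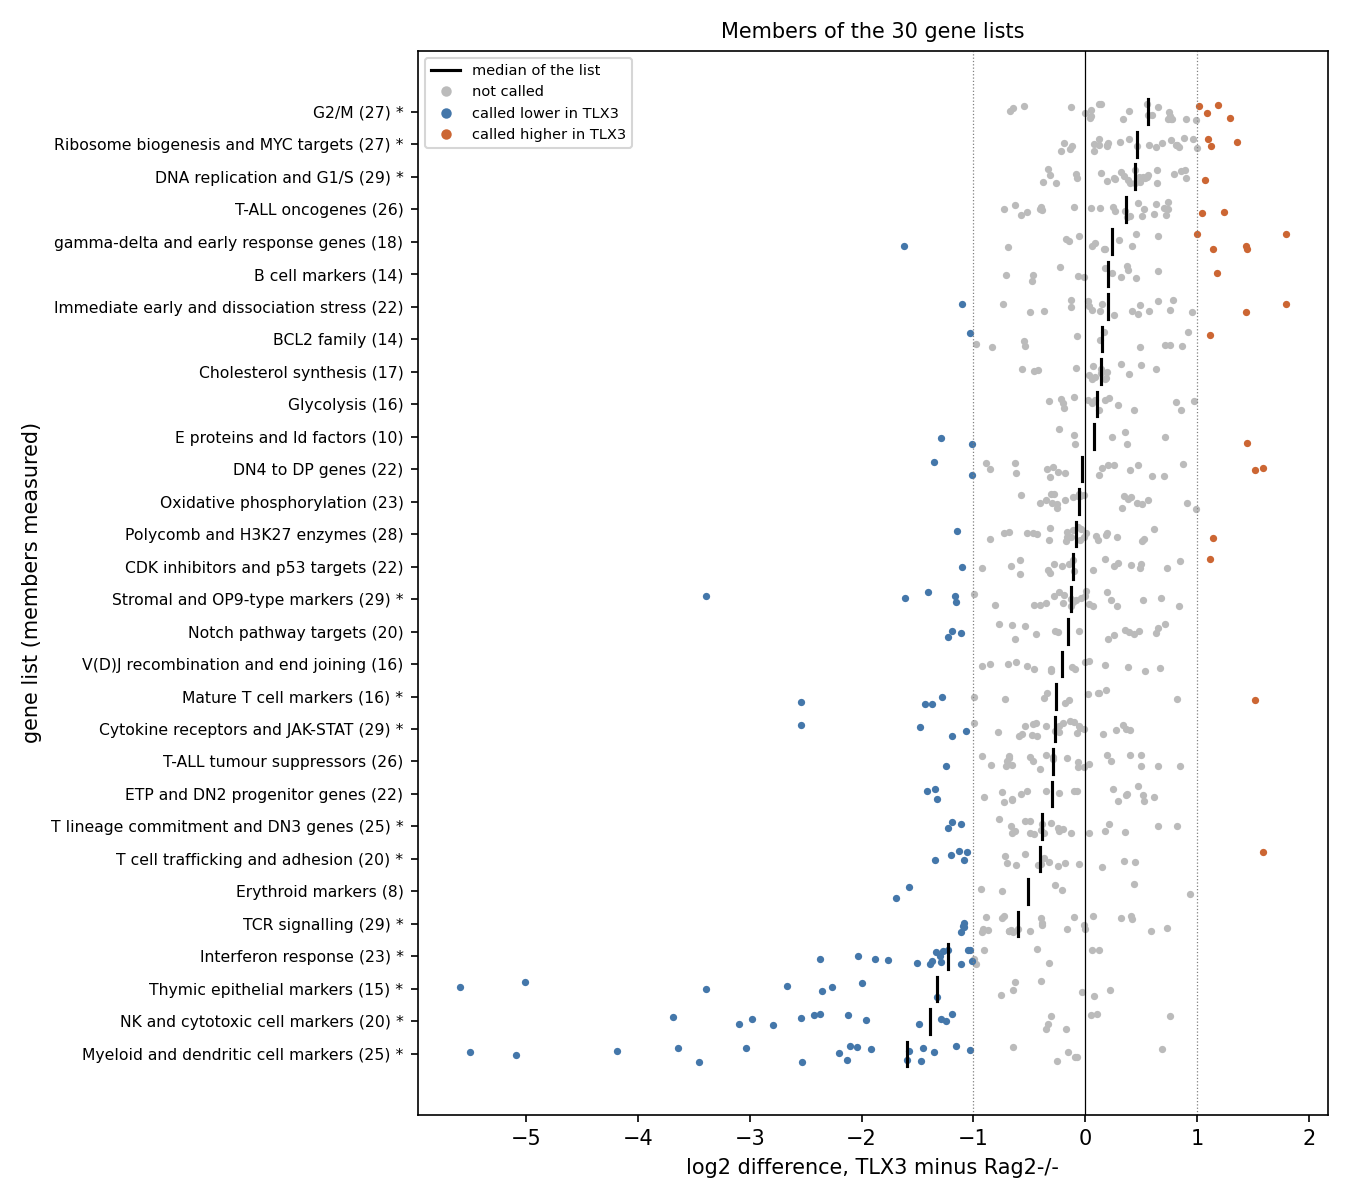
Log2 difference of each measured member (horizontal axis, TLX3 minus Rag2-/-) in 30 gene lists (vertical axis, with the number of members measured), orange for genes called higher, blue for genes called lower and grey for genes not called. Black ticks mark list medians, dotted lines a difference of 1 either way, and asterisks the 13 lists past the camera test, from a median of 0.57 for G2/M to -1.59 for myeloid and dendritic markers.

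Across the 30 lists tested, camera called 13, of which 10 were lower and 3 higher. With an estimated correlation it called 0, and fry, which asks whether a list moves one way on balance, called 19. When probe sets under the median level were left out, the T-lineage, cytokine, trafficking, stromal and mature T-cell lists lost the call (camera adjusted p of 0.138, 0.123, 0.125, 0.517 and 0.214) and the gamma-delta list gained it. With a filter at the 25th percentile, the stromal and mature T-cell lists lost it (0.0917 and 0.0596). Against lists matched on level and gene length, the stromal median was -0.13 against 0.04, with 9.66% as low. The G2/M, DNA replication and ribosome biogenesis medians (0.57, 0.44 and 0.46) stood against -0.14, -0.10 and -0.06.

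Among the 12 largest rises, Trdv2-2, a variable segment of the T-cell receptor delta chain, rose by 2.37 ± 0.16 (SE), from 4.68 to 7.05, and the small cytoplasmic RNA Rny1 by 2.17 ± 0.42, with a wide spread over the TLX3 arrays (7.91, 7.11 and 5.82). The neurofilament gene Nefh (1.86), the ribosome biogenesis factor Rrs1 (1.70), the respiratory chain subunit Cox6a1 (1.67), C2cd4b (1.65), Rps19 (1.58) and the mitochondrial serine hydroxymethyltransferase Shmt2 (1.46) were among them. Qk rose by 1.63 on its brightest probe set, but its probe sets disagreed, at 1.63, 1.01 and -0.73. Among the 12 largest falls outside the lists were Cbr2 (-4.29), the iron exporter Slc40a1 (-3.99), the prostaglandin-degrading enzyme Hpgd (-3.87), the complement gene C1qb (-3.56) and the microRNA locus Mir181b-1, which fell from 8.84 ± 0.22 to 5.27 ± 0.37 (SD, n = 3).

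Y-linked genes were measured in both groups. Eif2s3y fell by 1.33, Uty (-0.94) and Kdm5d (-0.50) passed the limma adjusted p only, and Xist, which marks an inactive X chromosome, was near 5 in both groups (5.14 and 5.06). Over the chromosomes, 0 of 20 passed camera among 9958 genes above the median level. With an estimated correlation or by fry, 0 passed at an adjusted p under 0.05. At an unadjusted p under 0.05 there was 1 by camera, with 0 at an estimated correlation and 12 by fry. The lowest camera adjusted p was 0.525, and chromosome medians ran from -0.30 to -0.06.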

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

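The tests of other splits, of other cells, of stage, of array scale and of gene length for the first and second patterns were written down after the results they bear on had been seen; the third pattern was noticed in the data, and its tests were written down before their values were seen.

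Signals appeared in probe sets outside the gene counts. Of the 6568 probe sets numbered before the genome-ordered ones, 244 were higher in the TLX3 arrays at a limma adjusted p under 0.05 and a difference of at least 1, and 2425 were lower, with a median of -0.75; what they target is not given in the sources used here. Of the 5231 tested probe sets with no gene listed, 302 were higher and 240 lower. The count of 1298 changed genes was set against other divisions of the arrays: 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many, and the highest of the others gave 0. With 10 splits, a share under 0.05 cannot be reached.

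The first pattern is the fall of thymic epithelial, myeloid and NK markers. A difference in array scale was argued against, since the median of the called members was -2.23 and stayed at -2.25 after cyclic loess. A candidate explanation is RNA of such cells in the Rag2-/- material. Over the Rag2-/- arrays the mean of the called epithelial, myeloid and NK members had a range of 0.85, 0.34 and 0.16 log2 units. These ranges were above 99.7%, 100% and 98.2% of level-matched random lists. The 3 means did not move together, being highest on replicates 3, 1 and 2 in that order. RNA of 3 kinds of cells could vary separately, so this order does not decide. Mean levels in the Rag2-/- and TLX3 arrays were 11.49 and 5.89 for Prss16, 10.74 and 6.55 for H2-Ab1, and 9.80 and 6.12 for Ccl5. In the TLX3 arrays, 8, 6 and 4 measured members of the epithelial, myeloid and NK lists were above the median. Among all measured members of each list, 0, 1 and 2 were also held by another list. Genes co-regulated within thymocytes could vary together too, the sort named in the labels would remove only cells with CD4 or CD8, and a change caused by TLX3 or by weeks of culture was not tested, so these stay open.

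The second pattern is the fall of Ptcra, Il2ra and Dtx1. Array scale was argued against, since their median was -1.10 after cyclic loess, although Ptcra alone (-0.97) lost its call. Dilution by other cells in the Rag2-/- material would make T-lineage genes higher in the TLX3 arrays, the opposite direction to this fall. The median was -1.19 with a largest SE of 0.14. Since the 3 genes were picked because they fell, that value restates the pattern and is no separate test of dilution. Passage beyond the DN3 stage cannot be told apart from other causes, since genes of the later stages went both ways, with a median of -0.029. An effect of TLX3, of the Rag2 genotype or of culture was not tested and stays open, as does a part in the fall of long genes described next. Random lists matched to the 3 genes on level and gene length had a median of -0.12. The choice of the 3 genes for their fall widens that gap, so it does not decide.

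The third pattern is the fall of a set of genes grouped as having transcripts held in the nucleus or spliced late. Its first members were noticed in these data, and only the further ones were listed before their values were seen. Neither property was measured here, and the set holds many genes of splicing factors, such as Srsf5 and Rbm39. All 13 members first noticed, among them Malat1 (-2.13), Clk1 (-1.83) and Clk4 (-1.63), were called lower, and of 24 further measured genes of this kind, written down before their values were seen, 9 were called lower and 0 higher, with a median of -0.92 against -0.14 for level-matched lists. Array scale was argued against, since that median was -0.82 after cyclic loess. A smaller share of unspliced or nuclear RNA on the TLX3 arrays may account for it: among 9964 genes above the median level, the 1993 with the longest gene length had a median log2 difference of -0.40 and the 1993 with the shortest 0.10, a gap of -0.50, and of -0.47 after cyclic loess. The way RNA was extracted, RNA quality, transcript length and a cellular change were not separated by this test.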

How the results depend on the processing

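Cyclic loess was chosen after the data were seen, and the other alternatives before. No called list changed direction. Across the 3 rescalings, the 25th percentile filter on dim probe sets, the variance model, array weights and the mean of a gene's probe sets, the counts of changed, higher and lower genes, of lists and, where run (not with the filter), of chromosomes stayed within 1.5 times their main values, but the genes were partly others: of the 288 higher genes, 191 were also called after quantile normalization again and 170 after cyclic loess, and of the 1010 lower ones 755 and 766. With no minimum difference, 8453 genes were changed, 4595 of them higher and 3858 lower, so most were higher. With limma treat at a minimum difference of 1, 129 were changed, 7 higher and 122 lower. A filter at the median level left 182 of the 288 higher genes and 947 of the 1010 lower ones. It drops probe sets with neither group mean above the median of probe sets. The higher calls thus held the larger share of dim genes, which may be background in both groups. With an estimated correlation, camera called 0 of 30 lists, against 13. A correlation above the preset was not the cause for every list. That of the mature T-cell list was estimated at 0.0019, under the preset 0.01, yet its unadjusted camera p rose from 0.0086 to 0.0499. The cause was not tested further. Leaving out each array gave 1036 to 1588 changed genes, 216 to 431 higher and 820 to 1157 lower, 13 to 14 lists and 0 chromosomes. The fewest changed genes came without TLX3 replicate 1, the array with the narrowest signal range. The share of higher genes among the calls was 22.2%, and 26.6%, 15.3% and 22.3% after quantile normalization again, equal medians and cyclic loess.

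Among 96 named genes, 9 lost the call after cyclic loess, 7 after quantile normalization again and 9 without TLX3 replicate 1. With limma treat 50 lost it. Of lists not called, the medians of the Notch, Polycomb and oxidative phosphorylation lists changed sign after quantile normalization again and cyclic loess, and that of the DN4 to double-positive list with the median filter. The replicate numbers are shared by the groups but did not pair the arrays: deviations of same-numbered arrays from their group means correlated at -0.11, 0.06 and -0.00, and not every array correlated best with its own number. With the replicate number as a replicate block, 1302 genes were changed, 289 higher and 1013 lower, and it changed no call among the named genes or lists. Leaving out probe sets by name endings was not run, because names on this platform carry none. Detection calls were not used here, so differences between dim probe sets are limited by a background that the values do not show.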

Other observations

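Genes in this part were chosen after their values were seen, as was the test on immediate early genes.

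Of 6 measured microRNA loci of the mir-181 family, 3 fell and 0 rose: Mir181b-1 (-3.57), Mir181a-1 (-2.18) and Mir181a-2 (-1.02). Of 9 variable segments of T-cell receptor genes with a single symbol, Trdv2-2 (2.37) and Trbv1 (1.22) rose and Trgv1 (-1.05) fell, with a median of 0.29, and -0.06 after cyclic loess. The X-linked long noncoding RNA Firre fell by 2.92. Of 17 killer lectin-like receptor genes, which are known from NK cells, 8 fell and 0 rose. The fixed NK list, of which 13 of 20 members fell, holds some of the same genes, so these counts overlap.

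Of 9 enzymes of serine and folate one-carbon metabolism, Shmt2 (1.46) and Mthfd1 (1.13) rose and none fell, Mthfd2 was at 0.82, and Phgdh (0.05) and Psat1 (-0.04) were not called. The median was 0.69, and 0.87 after cyclic loess. The amino acid transporter Slc7a5 (1.02), Mrto4 (1.43) and Ddx18 (1.20) rose. Of 34 histone genes, 4 rose and 0 fell, with a median of 0.44, and 0.41 after cyclic loess. Of 77 mitochondrial ribosomal protein genes, 1 rose and 0 fell, with a median of 0.25, and 0.40 after cyclic loess. The inhibitory receptor Pdcd1 (1.25) and the phosphatase Dusp4 (1.17) rose, and Cd5 (0.82) and Cd6 (0.88) passed the limma adjusted p only.

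The rises of Nr4a1, Egr1 and Id3 raised the hypothesis of a response to antigen-receptor signals, which wild-type but not Rag2-/- cells could receive through a rearranged receptor. The fixed list of immediate early genes had a median of 0.20 and a camera adjusted p of 0.22, so the camera test did not decide. At the limma adjusted p alone, 9 of its 22 measured members were higher and 4 lower, with Jun (-0.49) and Btg2 (-1.10) among the lower. Random lists matched on level and gene length had a median of 0.17, and 61.5% of them were as low. Those matched on level alone had a median of -0.01, with 94% as low. Fry, which does not set a list against other genes, called the list higher (adjusted p = 0.00533). Camera with an estimated correlation did not call it (adjusted p = 0.508).

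A probe set that the platform annotation lists for Kcnma1 was at 3.21, 12.24 and 12.65 on Rag2-/- replicates 1, 2 and 3. On the TLX3 arrays it was at 3.39, 4.90 and 4.54 (limma adjusted p = 0.073). Where its probes lie in the genome was not checked, so the value need not measure Kcnma1. A neighbouring probe set with no gene listed was at 4.62, 9.97 and 5.01 on the Rag2-/- arrays. Neither was called.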
